A study of Danio rerio with 4 samples.

How the data were processed

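The data are 1 table of values for 31953 genes in 4 RNA-seq libraries of zebrafish pharyngeal arch cells, with Ensembl gene identifiers and symbols side by side. Per the labels' protocols, embryos were kept at 28.5 °C until 27 hpf and then at 22 °C, and were dissociated when they had reached the form of the 36 hpf stage. Cells positive for both fli1a:GFP and sox10:DsRed were sorted into lysis buffer, RNA was purified with the RNeasy Micro kit, cDNA was made with the SMARTer kit, and libraries built with the Kapa Hyper prep kit were sequenced on a NextSeq 500 as 75-bp paired ends. Mutants were identified by ocular coloboma, and the sox10:Gal4 embryos, with or without UAS:Nr2f5, by genotyping fin biopsies at 24 hpf. The labels do not say whether the 2 mutant libraries came from separate clutches, and they give embryo and cell numbers for the mutants without assigning them to a replicate.

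Per the submitters' processing notes, TopHat2, Partek and the GRCz10 assembly were used. The notes give no versions, no annotation release, and no role for each tool. The deposited file calls its values TPM. The values, used as deposited by the authors, were taken as RPM, the reads of a gene per 1000000 reads, a scale that is assumed. No division by gene length was inferred, because most low values in a library, whatever the gene, are multiples of 1 common step. Within a tolerance of 0.02 read, 88.4%, 90.4%, 94.0% and 89.4% of values worth 0.5 to 1000 reads were whole multiples of that step in mutant 1, mutant 2, the UAS:Nr2f5 library and the control. The rest were fractional, so limma was not run on counts. Values were rounded to whole implied reads for the counting intervals, the limits for 0 reads, the chi-square between the mutants and the thinning described below. At the assumed scale the step implies 34787210, 22677738, 10127921 and 29943421 reads in total. The columns sum to 14.8% to 15.8% of that full scale, and the 10 most abundant genes hold 8.12% to 10.6% of each column. All columns of values were assigned to a library.

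Values were taken as log2(RPM + 1), and the 11391 genes with a mean of at least 1 RPM over the 4 libraries were tested. limma (lmFit, contrasts and eBayes with a trend) was fitted to all 4 libraries with 1 mean per group and no covariates, and p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. The fit has 1 residual degree of freedom, from the mutant pair, so that a limma adjusted p measures a difference against the spread of those 2 libraries and the lone libraries are assumed to vary like them. The test had been planned for TPM and was kept for RPM, since both are normalised values without whole counts. A size rule counted genes at least 2-fold apart on the same log scale, in both mutants where they were compared. No paired analysis was possible, because the control and the UAS:Nr2f5 group have 1 library each and the labels name no pairs.

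For the library labelled UAS:Nr2f5 against the control, with 1 library each, no p-value is given. Fold differences there carry exact Clopper-Pearson 95% intervals on the implied reads. A count of 0 was set to the limit of 3 reads in that library (0.296 RPM in the UAS:Nr2f5 library, 0.0862 and 0.132 in the mutants, 0.100 in the control). Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Libraries differ by more than that: between the 2 mutants the chi-square per gene, near 1 under counting error alone, was 10.4 over 13823 genes with at least 20 reads. The 26 gene lists hold 478 members, of which 469 were matched to the table, 17 of them through the reference table of gene names. Lists were read by the median log2 difference of their members with a mean of at least 1 RPM, and by its percentile among 10000 random lists of the same size matched on expression in 20 bins. Medians outside the central 95% are called outside the random range, as a description of these libraries. There were 130 such medians. Some genes and 1 list are not reported here. The other lists are the nr2f family, upper jaw, lower jaw, cartilage, bone and dermal matrix, early neural crest, frontonasal and anterior identity, Hox genes of posterior arches, Bmp, Wnt, Fgf and Hedgehog response, retinoic acid, Notch response, proliferation, immediate early and heat shock, endothelial, red blood and white blood cells, epidermis and endoderm, muscle, neurons, glia, pigment cells, and otic, eye and lens. The upper jaw list shares 6 genes with the Notch list and 2 with the nr2f family, the lower jaw list 2 with Hedgehog and 1 with Bmp, and pigment and white blood cells share 1.

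Groups, lists, tests, thresholds and the rule for naming genes were chosen before the data were examined. The rule names the nr2f family, the 10 genes with the largest difference in each direction in each comparison among those with a mean of at least 5 RPM, any member of the jaw lists, the 4 members of each list with the largest differences in a comparison, and the 10 genes with the largest opposite differences. It leaves out clone names and mitochondrial, ribosomal and haemoglobin genes from the top genes. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 RPM, median-ratio scaling, quantile normalization, values without mitochondrial, haemoglobin and the 20 most abundant genes, other fold and p thresholds, limma without a trend or on 3 libraries, and each mutant left out. A scaling to the early neural crest list and a thinning of all libraries to the implied reads of the shallowest were added after the data had been seen.

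Tested on simulated data with 200 changed genes among 11391, limma recovered 0%, 51% and 81% of genes changed 2-, 4- and 8-fold in the mutants against the control, with 1, 6 and 6 false calls. For the mutants against the UAS:Nr2f5 library it recovered 0%, 50% and 81.5%, with 0, 6 and 15 false calls. Every simulated library, the lone ones included, had counting error and a scaled-down form of the mutant pair's spread. The false calls therefore do not cover lone libraries that vary more than the mutants. The percentile rule called 100 of 100 lists shifted by 1 on the log2 scale and 5 of 100 unshifted lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. No genome of the assembly used was at hand, so no coordinates are given.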

Results

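RNA was sequenced from zebrafish (Danio rerio) pharyngeal arch cells, the cells that build the jaw skeleton, at the 36 hours post-fertilization (hpf) stage. The cells had been sorted for 2 transgenes at once, fli1a:GFP, active in arch neural crest and in blood vessels, and sox10:DsRed, active in the neural crest lineage. There were 4 libraries in 3 groups. Embryos mutant for both nr2f2 and nr2f5 gave 2 libraries, named mutant 1 and mutant 2. Embryos with the sox10:Gal4 driver alone gave 1 control library. Embryos with sox10:Gal4 and UAS:Nr2f5, in which Gal4 is meant to switch on Nr2f5 in the crest, gave 1 library. The mutant replicates came from 37 and 84 embryos (18858 and 30655 cells), the control from 69 embryos (86517 cells) and the UAS:Nr2f5 library from 84 embryos (56866 cells). Values were taken as RPM, the reads of a gene per 1000000 reads of its library, a scale that is assumed. In these units 1 read was worth 0.0287 in mutant 1, 0.0441 in mutant 2, 0.0334 in the control and 0.0987 in the UAS:Nr2f5 library. If the scale holds, the values imply 34787210, 22677738, 29943421 and 10127921 reads in total. Of these reads, 5286230, 3590905, 4467228 and 1498321 were in genes. The control and the UAS:Nr2f5 group have no replicates. Mutant values are given as mean ± SD with n = 2.

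The nr2f genes were read first, because they check the labels. Nr2f proteins are orphan nuclear receptors (COUP-TFs), and the series asks what they do for the identity of the upper jaw. In the mutants, nr2f5 was at 12.2 and 14.7 RPM (13.4 ± 1.76), against 28.8 in the control, a 2.15-fold lower mean (log2 difference −1.05 ± 0.20 SE). That gene passed limma's test against the control when adjusted over the list alone (adjusted p = 0.0124) and not over all 11391 genes (adjusted p = 0.0910). The other mutated gene, nr2f2, was at 38.9 and 30.9 RPM in the mutants and 41.4 in the control (limma adjusted p = 0.692). A transcript level does not check a mutation that leaves the transcript in place, and the labels do not describe the alleles. In the library labelled UAS:Nr2f5, nr2f5 stood at 30.3 RPM, a ratio of 1.05 to the control with a 95% counting interval of 0.920 to 1.199. The transgene's gain is thus not seen at the nr2f5 gene, and each direction drawn from this library below rests on its label. It is not known whether reads of the transgene would be assigned to that gene. Among the family's other members in that library, nr2f1b was at 18.3 RPM against 29.9 in the control, nr2f2 at 28.1 against 41.4, and nr2f1a at 41.3 against 46.8. nr2f6a was at 19.4 against 16.1 and nr2f6b at 6.62 against 11.1. No family member was 2-fold apart on the log2(RPM + 1) scale between those 2 libraries.

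The comparison of the library labelled UAS:Nr2f5 with the control asks what more Nr2f does to genes of the lower and upper jaw. Lower jaw genes were among the genes furthest below the control in it, while upper jaw genes were not 2-fold apart, and genes of muscle, epidermis and lens were higher. The Dlx homeobox genes, which pattern the arches along the dorsoventral axis, led the difference. dlx4b was listed at 0 against 6.98 RPM in the control, at least 23.6-fold lower when set against the 3 reads (0.296 RPM) that a count of 0 allows. dlx6a was listed at 0 against 4.27 RPM, at least 14.4-fold lower. These bounds leave out the control's own counting error, and the 95% counting intervals of the ratios start at 19.0-fold and 11.6-fold. dlx4a was 8.66-fold lower (counting interval 5.42 to 14.7), at 1.78 against 15.4 RPM. dlx5a was 7.96-fold lower (5.30 to 12.53), at 2.37 against 18.9 RPM, and dlx3b 5.09-fold lower (3.34 to 8.13).

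Other ventral arch genes were also lower in that library. nkx3.2, the gene of the jaw joint, was 6.27-fold lower (3.60 to 11.9). hand2, the bHLH factor of the ventral arch, was 4.39-fold lower (3.11 to 6.38). gsc was 3.21-fold lower (2.12 to 5.06) and foxf2a, a forkhead gene of the Hedgehog response, 2.43-fold lower (1.75 to 3.46). Of the 21 measured members of the lower jaw list, 10 were at least 2-fold lower on the log2(RPM + 1) scale and 0 were higher. The list's median log2 difference was −0.61, at percentile 0.11 of 10000 random lists matched on expression, and it was −0.46 after median-ratio scaling and −0.26 when scaled to early neural crest genes. That crest scaling is 1 factor per library, so it moves every list median alike, by 0.35 here, by −0.39 for the mutants against the control and by −0.74 for the mutants against the library labelled UAS:Nr2f5, and leaves the percentiles as they are. With both zeros set to the 3-read floor it is also −0.61, which could not be otherwise since both genes lie below the median either way. Among the members under 2-fold apart, the Endothelin receptor gene ednraa was at 21.3 against 19.7 RPM and the protease gene furina at 22.4 against 16.1, while mef2ca and plcb3 were lower, at 4.25 against 6.85 and 5.33 against 7.38. igfbp5b (18.6 against 18.5), gata3 (10.9 against 11.6) and bmp4 (2.37 against 2.07) were close to equal.

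**Figure D1:**
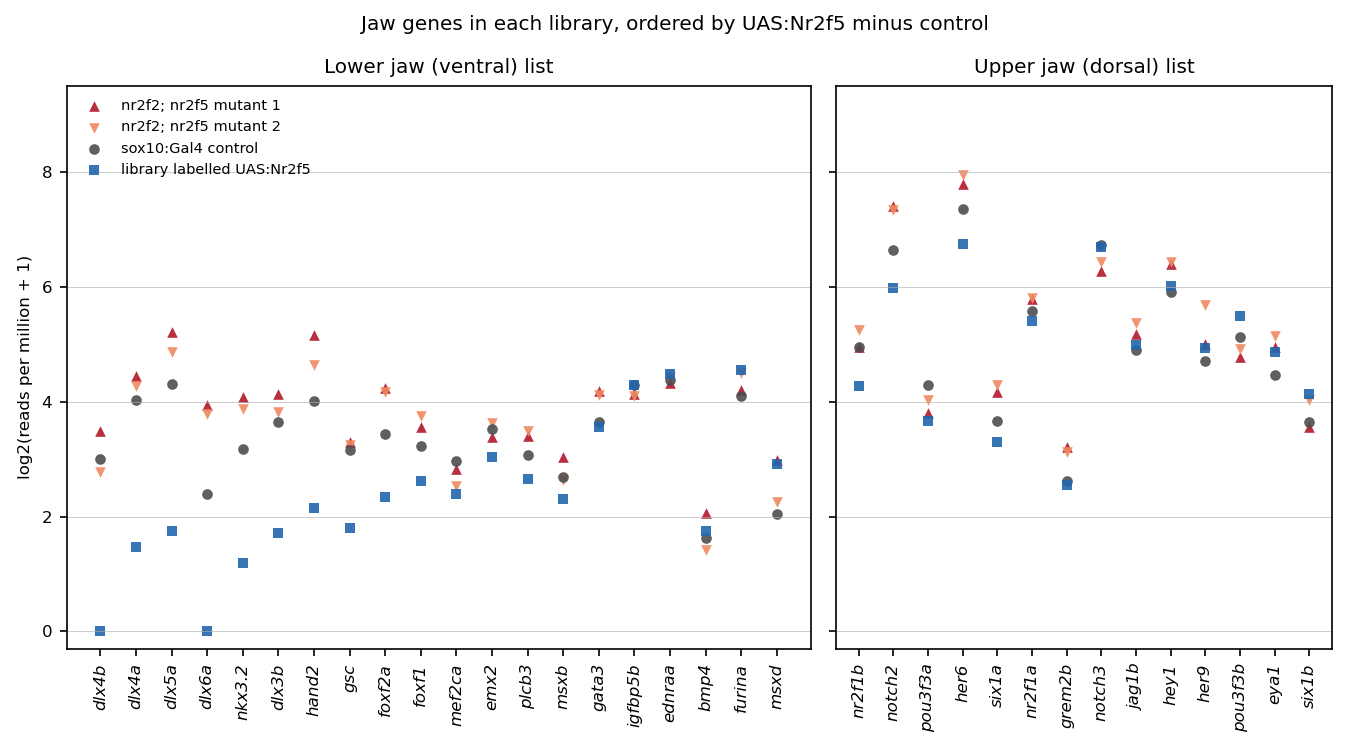
Jaw genes, all but 1 of the measured members, in each of the 4 libraries, as log2(RPM + 1), with lower jaw genes on the left and upper jaw genes on the right, ordered by the difference between the library labelled UAS:Nr2f5 (blue squares) and the sox10:Gal4 control (grey circles), and with both mutants as triangles. dlx4b and dlx6a are listed at 0 in the library labelled UAS:Nr2f5, and none of the 14 upper jaw genes differs 2-fold between it and the control.

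Upper jaw genes did not differ 2-fold in either direction. The Notch ligand jag1b, which patterns the dorsal arch, was at 30.6 against 28.9 RPM, and its target hey1 at 63.5 against 59.1. The Notch effector her6 was 1.53-fold lower (1.43 to 1.63) and the receptor gene notch2 1.595-fold lower (1.46 to 1.74). pou3f3b was 1.31-fold higher (1.17 to 1.46) and pou3f3a 1.59-fold lower (1.297 to 1.95). eya1 was 1.33-fold higher (1.15 to 1.53), six1b 1.42-fold higher (1.18 to 1.72) and six1a 1.32-fold lower (1.04 to 1.68). her9 (29.5 against 25.0), grem2b (4.84 against 5.14) and notch3 (102 against 105) lay close together. The list's median was −0.06, at percentile 94.3, inside the central 95% of random lists, and it was 0.11 after median-ratio scaling and 0.29 when scaled to early neural crest genes.

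Cartilage genes differed in both directions in that library. Of the 20 measured, 3 transcription factor genes were at least 2-fold lower on the log2(RPM + 1) scale, barx1 by 4.67-fold (3.57 to 6.22), sox5 by 2.26-fold (2.04 to 2.504) and sox9a by 2.06-fold (1.78 to 2.38). The collagen genes col9a1b and col11a2 were 2.17-fold higher (1.80 to 2.61) and 2.305-fold higher (1.98 to 2.68), while the collagen gene col9a1a, named after its values were seen, was at 6.22 against 12.8 RPM. The list's median of −0.16 (0.02 and 0.20 under the median-ratio and crest scalings) lay at percentile 66.1. In the bone and dermal matrix list, sp7, the osteoblast factor, was 3.90-fold higher (2.63 to 5.82), col1a1b 2.01-fold higher (1.90 to 2.12) and phex 2.96-fold higher (1.82 to 4.79), and the median was 0.43 (percentile 99.6). Early neural crest genes had a median of −0.25 (percentile 35.4; 0.10 under the crest scaling). Of those 15 genes, dlx2a was 2.77-fold lower (2.20 to 3.53), foxd3 was 4.68-fold higher (2.47 to 9.18), and the others were under 2-fold apart on the log2(RPM + 1) scale.

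Markers of other cell types differed alongside these groups. Muscle genes were above the control in the library labelled UAS:Nr2f5 for 21 of 21 measured members, 19 of them at least 2-fold, with a median of 1.74, and the list's summed values were 5339 against 1635 RPM. pvalb2, a calcium buffer of fast muscle, was 4.84-fold higher (4.55 to 5.15), and pvalb1 3.83-fold higher (3.61 to 4.08). Epidermal and endodermal genes were at least 2-fold higher for 20 of 23 members, with a median of 1.58. Among these, the keratin gene krt4 was at 1508 against 504 RPM, and krt91 was 7.02-fold higher (5.62 to 8.88). Lens crystallins headed the highest genes, with cryba4 21.5-fold higher (16.4 to 28.8) and crybb1 13.2-fold higher (11.2 to 15.6). The otic, eye and lens list as a whole had a median of 0.07 (percentile 56.6), with 4 of 11 members at least 2-fold higher and 3 lower. Pigment cell genes were at least 2-fold higher for 7 of 12 members and lower for 1, with a median of 1.04 (percentile 100). The melanin genes slc45a2 and tyr were 9.71-fold higher (5.25 to 19.1) and 6.71-fold higher (4.16 to 11.1). Neuronal genes had a median of 0.44 (percentile 98.9) with 0 of 17 at 2-fold.

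Proliferation genes were lower as a list, with a median of −0.47 (percentile 0.695), and mcm3, of the replicative helicase, was 2.13-fold lower (1.84 to 2.49). Other genes far lower in that library were gpr161, a ciliary receptor of the Hedgehog pathway, at 1 read and 49.0-fold lower (8.66 to 1950), the condensin gene ncaph2, 13.1-fold lower (5.50 to 40.7), and sim2, 8.46-fold lower (4.77 to 16.5).

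Over all 11391 genes, 1818 were at least 2-fold apart between these libraries, 773 higher and 1045 lower in the library labelled UAS:Nr2f5. The median gene differed by −0.11, and relative to it 961 were higher and 803 lower. A median-ratio scaling gave 1027 higher and 829 lower (median gene 0.03), and a scaling set on early neural crest genes 1584 higher and 418 lower (median gene 0.24). There is 1 library on each side, so these intervals cover counting error only and no p-value is given. In a limma contrast that borrows the spread of the mutant pair, 0 genes passed and 2411 had an unadjusted p under 0.05.

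**Figure D2:**
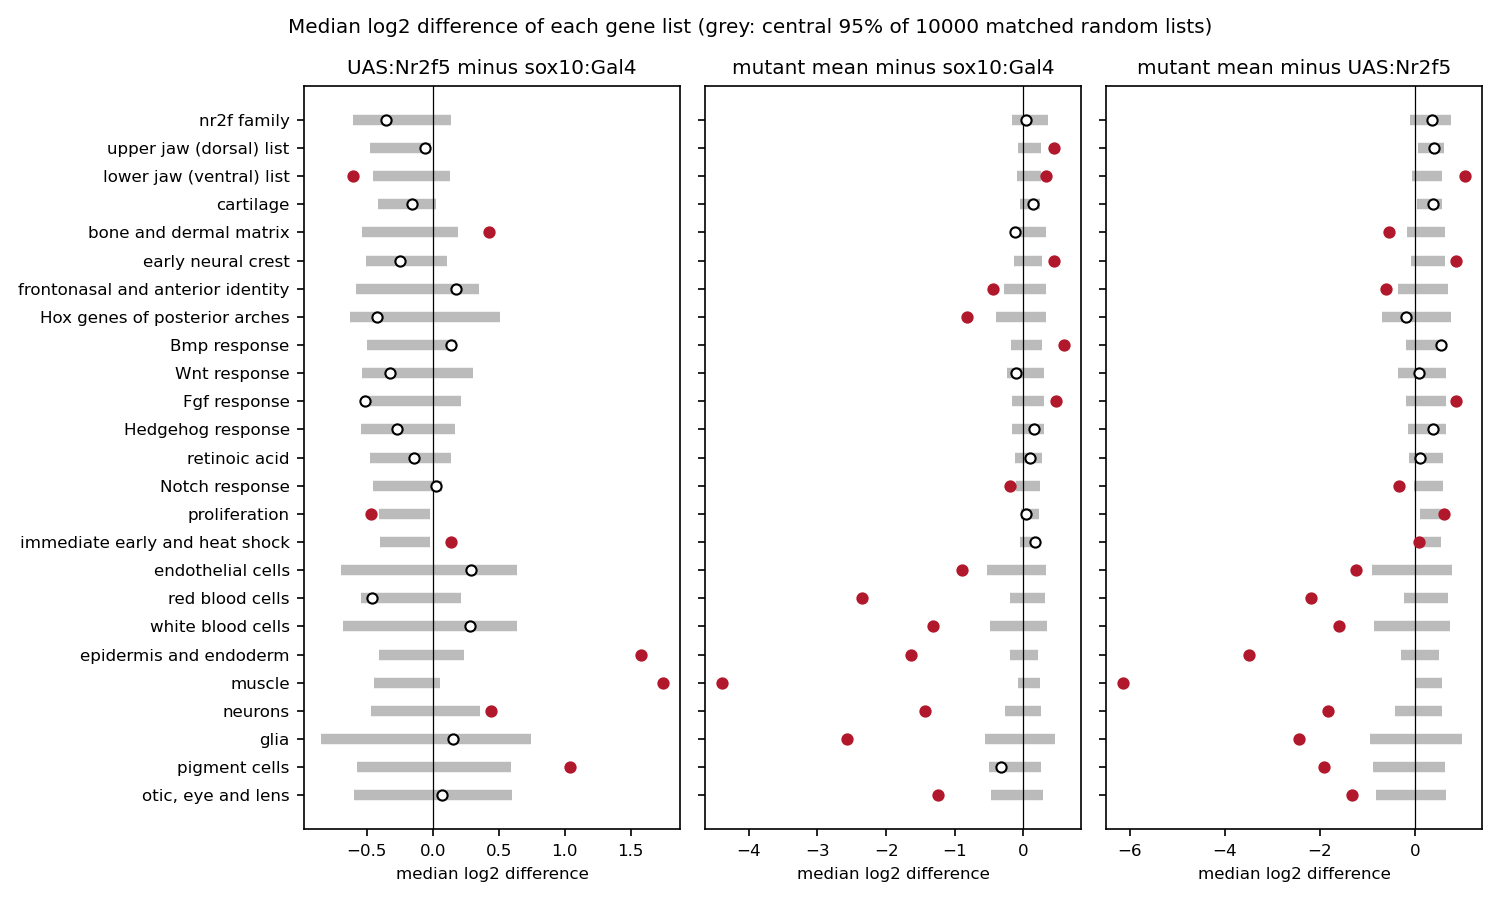
Median log2 difference of all but 1 of the 26 gene lists in 3 comparisons, with the central 95% of 10000 expression-matched random lists in grey and medians outside it in red. The lower jaw list lies at −0.61, 0.33 and 1.04 from left to right, and the muscle list at 1.74, −4.39 and −6.13.

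The comparison of the double mutants with the control asks what loss of Nr2f2 and Nr2f5 does. By the labels, the control carried the sox10:Gal4 driver and was biopsied at 24 hpf, and neither is given for the mutants. Effects of the driver and the biopsy cannot be told apart from those of the mutations here. The genes that differed most were those of cell types other than the arch crest, and they were lower in the mutants. The myosin gene myhz1.1 was at 5.02 ± 2.76 RPM against 207 in the control, 41.2-fold lower (limma adjusted p = 0.00459). pvalb1 fell 46.2-fold (1.31 ± 0.0511 against 60.7 RPM, limma adjusted p = 0.00174), the titin gene ttnb 27.7-fold (11.4 ± 3.78 against 317), tpma 32.7-fold and the muscle creatine kinase gene ckmb 29.1-fold. Of 21 measured muscle genes, 18 fell over all genes tested and 19 when adjusted over the list alone, and the median was −4.39.

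Epidermis and endoderm followed, with 5 of 23 genes fallen over all genes, 18 adjusted over the list alone, and a median of −1.63. krt4 was at 39.7 ± 20.6 RPM against 504, 12.7-fold lower (limma adjusted p = 0.0253). Red blood cell genes were lower in both mutants for 11 of 11 members, with a median of −2.35, 0 fallen over all genes and 10 adjusted over the list alone. The embryonic globin gene hbae3 was at 32.3 ± 21.04 against 195 RPM. Neuronal genes fell for 2 of 17 members over all genes and 12 adjusted over the list alone (median −1.43), and phox2bb rose adjusted over the list alone. The neuronal RNA-binding gene elavl3 fell 8.15-fold (limma adjusted p = 0.00454). In the glia list 3 of 5 genes fell over all genes and 4 adjusted over the list alone, while erbb3b rose adjusted over the list alone (median −2.57). The myelin protein gene plp1a fell 13.9-fold (adjusted p = 0.0232), and the astroglial filament gene gfap 13.6-fold. The early neural crest list did not share this direction, with a median of 0.45 (percentile 100).

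**Figure D3:**
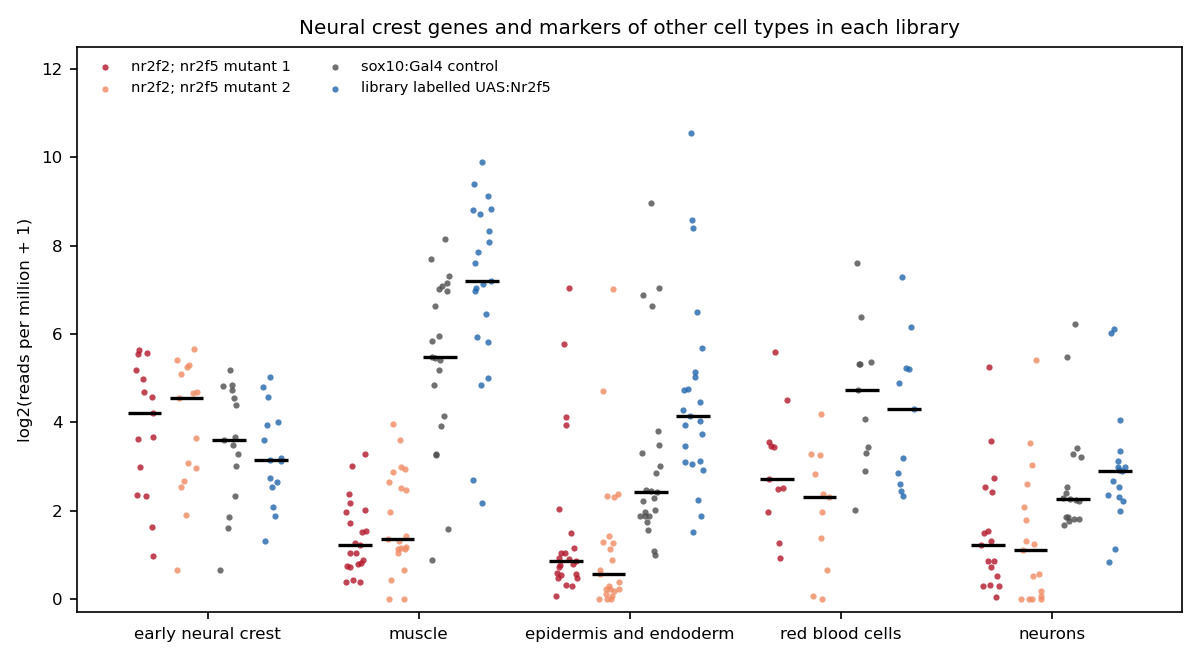
Genes of the early neural crest and of 4 other cell types in each library, as log2(RPM + 1), with 1 point per gene and a bar at the median. Muscle genes are lowest in both mutants, higher in the control and highest in the library labelled UAS:Nr2f5, with summed values of 45.5, 75.1, 1635 and 5339 RPM.

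Notch pathway genes split in the mutants. The receptor genes notch1b (13.0 ± 0.483 against 70.5 RPM, 5.42-fold) and notch1a (2.75-fold), and the ligand gene dla (5.01 ± 0.157 against 28.2 RPM, 5.62-fold), fell with limma adjusted p of 0.00459, 0.0370 and 0.0125. The ligand gene dld was lower without passing over all genes (4.01 ± 2.42 against 21.6, adjusted p = 0.0884). notch2 was at 165 ± 6.15 against 98.8 RPM and passed only when adjusted over the list alone (adjusted p = 0.0154 there, 0.0683 over the upper jaw list, which also holds it, and 0.125 over all genes). Of 19 members, 3 fell and 0 rose over all genes, with 7 and 2 adjusted over the list alone, and the median was −0.20 (percentile 0.12). Genes of the neuron and glia lists were lower in the same libraries (medians −1.43 and −2.57), and the shares of neural cells were not measured. In the library labelled UAS:Nr2f5 the Notch list had a median of 0.03 against the control (percentile 95.3). For the mutants against that library its median was −0.34 (percentile 0.03). There 7 of 19 members fell and 2 rose over all genes, with 8 and 2 adjusted over the list alone.

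Genes of both jaw lists lay slightly above the control in the mutants. The lower jaw list had a median of 0.33 (percentile 99.7), with 14 of 21 members above the control in both mutants and 2 below in both. No member passed limma over all genes. Adjusted over the list alone, 2 genes passed, among them dlx6a (13.6 ± 1.06 against 4.27 RPM, 3.19-fold, limma adjusted p = 0.0366). hand2 was at 29.3 ± 7.80 against 15.2 RPM (adjusted p = 0.225 over all genes) and dlx5a at 32.2 ± 5.75 against 18.9 (0.244). The upper jaw list also had a higher median, 0.44 (percentile 100), with 9 of 14 members above the control in both mutants, 3 below, and 0 passing in either way of adjusting. Its members hey1 (84.5 ± 0.886 against 59.1 RPM), her6 (233 ± 17.8 against 163) and jag1b (38.0 ± 3.74 against 28.9) were higher, and pou3f3a (14.1 ± 1.601 against 18.5) and pou3f3b (27.9 ± 1.85 against 33.9) were lower. Without mutant 1 the lower jaw median was 0.24, inside the range of random lists, and scaled to early neural crest genes it was −0.05, while the upper jaw median was 0.06 under that scaling.

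Early crest and signalling genes were in part higher in the mutants. In the early neural crest list 4 of 15 genes rose adjusted over the list alone and 0 over all genes, among them sox10 (21.2 ± 5.25 against 8.72 RPM) and snai2, an epithelial-to-mesenchymal factor (41.5 ± 6.08 against 19.9). The Bmp response list had a median of 0.59 (percentile 100; 0.20 under the crest scaling), with 3 of 15 genes risen adjusted over the list alone and 0 over all genes. id1, a direct Bmp target, was at 119 ± 25.0 against 65.0 RPM. The 3 genes that rose over all genes were nrp1a, a semaphorin and VEGF co-receptor (54.8 ± 6.01 against 21.1 RPM, 2.60-fold, limma adjusted p = 0.0477), ret, a receptor of enteric crest cells (12.4 ± 2.43 against 2.37, adjusted p = 0.0499), and si:dkeyp-3b12.11. The last is named after its values were seen. Among the highest without passing were cited2, ctgfb, phox2bb, ltbp3 and igf2b, the last at 36.2 ± 0.758 against 15.8 RPM (adjusted p = 0.0568).

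In all, limma called 118 of 11391 genes, 3 risen and 115 fallen, and all 118 were also at least 2-fold apart in both mutants, as were 676 genes in total (66 higher, 610 lower; 1145 for mutant 2 alone and 929 for mutant 1 alone). The test has 1 residual degree of freedom, from the mutant pair, and takes the lone control to vary as the mutants do. The count was 0 without the filter on low values, after quantile normalization, or with libraries thinned to 1 depth (3803, 1457 and 1205 genes at an unadjusted p under 0.05), 413 (154 risen, 259 fallen) among genes with a mean of at least 5 RPM, and 1500 (28 risen, 1472 fallen) under the crest scaling, which moves the median gene from 0.03 to −0.35.

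The mutants against the library labelled UAS:Nr2f5 set loss against the intended gain without the control. The driver and the biopsy differ by label in this comparison too. Lower jaw genes rose in the mutants relative to that library. dlx5a was 13.6-fold higher (32.2 ± 5.75 against 2.37 RPM, log2 difference 3.29 ± 0.23 SE, limma adjusted p = 0.00227). dlx6a and dlx4b were at least 46.0-fold and 27.1-fold higher against the 3-read floor, and dlx4a was 11.004-fold, nkx3.2 11.5-fold, hand2 8.49-fold and dlx3b 6.57-fold higher. In the lower jaw list 11 of 21 genes rose over all genes and 0 fell, 13 rose adjusted over the list alone, and the median was 1.04 (percentile 100; 0.30 under the crest scaling). The 10 that did not pass over all genes include ednraa, igfbp5b, furina and bmp4, each under 1.2-fold apart. In the upper jaw list 4 of 14 genes rose (notch2, her6, six1a and nr2f1b) and pou3f3b fell, by either way of adjusting, and the median of 0.40 (−0.34 under the crest scaling) lay at percentile 66.6. nr2f5 fell 2.26-fold in the mutants (adjusted p = 0.0195).

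Cartilage genes changed in both directions. barx1 was 7.46-fold higher in the mutants (42.0 ± 4.39 against 5.63 RPM, adjusted p = 0.00227), sox9a 3.54-fold and sox5 3.11-fold. The collagen genes col11a1a and col9a1b fell 2.997-fold and 10.97-fold, while col9a1a, named after its values were seen, rose 2.26-fold (adjusted p = 0.0337). The cartilage list had 6 genes risen and 3 fallen of 20 over all genes, and 6 and 6 adjusted over the list alone. In the early neural crest list 7 of 15 rose and 0 fell by either adjustment, with snai2 at 3.72-fold, sox10 at 3.69-fold and dlx2a at 3.40-fold. In the bone and dermal matrix list col1a1b fell 6.30-fold (adjusted p = 0.00147) and col5a1 rose 1.90-fold. Other genes with the largest rises were gpr161 (7.54 ± 1.06 against 0.0987 RPM), ncaph2 (18.6-fold) and f3b, which encodes tissue factor (8.84-fold).

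The other cell types fell in the same contrast. Muscle genes fell for 20 of 21 members over all genes and 21 adjusted over the list alone (median −6.13), and pvalb1 fell 177-fold (adjusted p = 0.000182). Epidermal genes fell for 20 of 23 by either adjustment, with 1 risen over the list alone (median −3.49). Neuronal genes fell for 12 of 17 (14 adjusted over the list alone), and 2 rose. Pigment genes fell for 8 of 12 (9 over the list alone) and 1 rose, ltk, a receptor of iridophores. In the otic, eye and lens list 6 of 11 fell by either adjustment, crybb1 by 211-fold, and oc90, of the otoconia, rose 9.43-fold. Proliferation genes rose for 8 of 25 over all genes and 9 adjusted over the list alone, with a median of 0.60 (percentile 99.6; −0.14 under the crest scaling).

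limma called 2287 genes, 1271 risen and 1016 fallen. The split followed the scaling, with 825 risen and 1242 fallen after median-ratio scaling, 286 and 488 after quantile normalization, and 367 and 4602 under the crest scaling (median gene 0.17, or −0.57 under it), while 0 genes passed without the filter or with libraries thinned to 1 depth (5270 and 3143 at an unadjusted p under 0.05). By size, 2143 genes were at least 2-fold apart in both mutants (1028 higher, 1115 lower), and 777 higher and 1333 lower after median-ratio scaling, or 158 higher and 2691 lower when scaled to early neural crest genes.

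Genes that differed in opposite directions under loss and intended gain were counted against the shared control. There were 170, of which 161 were lower in both mutants and higher in the library labelled UAS:Nr2f5, and 9 the reverse. Muscle and lens genes led the 161, with crybb1l1, crybb1, pvalb2, murcb and the muscle calcium channel gene ryr1b first, and 36 of them belong to the lists of other cell types (18 muscle, 15 epidermis). Among the 9 was dlx6a, at 13.6 ± 1.06 RPM in the mutants, 4.27 in the control and 0 in the library labelled UAS:Nr2f5, with oc90 beside it (7.45 ± 0.375, 2.94 and 0.790). By direction alone, 12 of 21 lower jaw genes and 5 of 14 upper jaw genes lay below the control in the library labelled UAS:Nr2f5 and above it in both mutants, as did 9 of 15 early neural crest, 8 of 13 Fgf response and 9 of 25 proliferation genes, and 2558 of all 11391 genes (22.5%). Another 30 genes differed the same way in both comparisons (10 higher, 20 lower). In 100 simulated sets with no effect, all libraries were given the spread of the mutant pair. There the shared control alone gave 1.58 opposite genes on average (at most 5) and 79.1 in the same direction. These sets hold no difference in cell mixture between libraries, so they do not give the number to set against 170 if Nr2f had no effect. Independent lists of these sizes would share 6.05 and 41.4 genes in the 2 opposite classes and 4.48 and 56.0 in the 2 same-direction classes. Across genes, which are not independent replicates, the 2 sets of differences had r = −0.145 against a simulated 0.577, and a covariance of −0.0656 against 0.0930. The control is 1 library and could not be split, so its share in these counts was not measured.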

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

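The crest scaling and the thinning were chosen after the data had been seen, and for every value below the cause was not tested, except where the setting itself changes the size asked for or the genes or libraries tested. Genes at least 2-fold apart between the library labelled UAS:Nr2f5 and the control (1818) numbered 2922 and 212 with pseudocounts of 0.1 and 5, 484 at a mean of at least 5 RPM, 4369 and 129 at 1.5-fold and 4-fold, and 0 by limma with the mutants' spread (2411 at an unadjusted p under 0.05). For both mutants against the control (676), the same settings without limma gave 1164, 154, 219, 1594 and 136, and leaving out a mutant gave 929 to 1145 (1145 without replicate 1). For both mutants against the library labelled UAS:Nr2f5 (2143), pseudocount 5 gave 492, a mean of at least 5 RPM 668, and 1.5-fold and 4-fold 4198 and 474. Genes in opposite directions (170) numbered 383 and 57 with the pseudocounts, 100 at a mean of at least 5 RPM, 347 under the crest scaling, and 497 and 7 at 1.5-fold and 4-fold.

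limma's count for the mutants against the control (118) was 22 with pseudocount 0.1, 0 with no filter (3803 at an unadjusted p under 0.05), 413 at a mean of at least 5 RPM, 0 after quantile normalization (1457), 1500 under the crest scaling, 0 after thinning (1205), 24 without a trend, 350 on 3 libraries and 319 at an adjusted p under 0.10. Against the library labelled UAS:Nr2f5 (2287) it was 1449 with pseudocount 0.1, 0 with no filter (5270), 774 after quantile normalization, 4969 under the crest scaling, 0 after thinning (3143) and 3633 at an adjusted p under 0.10. Leaving out a mutant leaves limma no residual degree of freedom, so no test was run there.

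The lower jaw median for mutants against the control (0.33) was −0.0534 under the crest scaling and 0.24 to 0.45 with a mutant left out, inside the random range without replicate 1. The proliferation median for mutants against the library labelled UAS:Nr2f5 was −0.14 under the crest scaling. The immediate early and heat shock median there (0.07) was −0.15 after median-ratio scaling, −0.12 after quantile normalization, −0.0142 without mitochondrial, haemoglobin and the top 20 genes, −0.67 under the crest scaling and −0.0048 after thinning. Over all lists in the 3 comparisons, the 7 negative medians just given turned in sign while outside the random range, 666 medians kept their direction and their side of the random range, 42 turned in sign while inside it under both settings, 15 came to lie outside it and 12 inside it. That tally does not follow the medians of single mutants against the control through the other settings. Among those, the upper jaw median of mutant 1 went from 0.29 to −0.077 under the crest scaling. The immediate early and heat shock median of mutant 2 went from 0.41 to −0.0013 under it. Both lay outside the random range. Of the values of single named genes, 364 stayed within their error, 176 moved beyond it and 0 turned in sign beyond it. Depth limits the library labelled UAS:Nr2f5 most, where 1 read is worth 0.0987 RPM.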

Other observations

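Position and signalling genes differed beside the jaw genes. Hox genes of the posterior arches lay below the control in the mutants, with a median of −0.82 (percentile 0.10), 0 of 8 passing limma over all genes and 3 fallen adjusted over the list alone: hoxa3a (2.73 ± 0.363 against 8.25 RPM), hoxb3a (9.91 ± 0.147 against 19.7) and hoxb5a. Their median was −0.42 (percentile 11.3) in the library labelled UAS:Nr2f5. The frontonasal list had a median of −0.45 in the mutants (percentile 0.17) with 0 of 10 passing, and 0.17 (percentile 88.7) in the library labelled UAS:Nr2f5. Against that library, the frontonasal median in the mutants was −0.61 (percentile 0.34). Of the 10 genes, 2 fell and 1 rose over all genes, with 4 and 1 adjusted over the list alone. pax7a fell (log2 difference −2.18, limma adjusted p = 0.0357), while foxd1, a forkhead gene, rose 2.23-fold (limma adjusted p = 0.0182). Fgf response genes had medians of 0.48 in the mutants (percentile 100, 0.10 under the crest scaling, 0 of 13 passing) and −0.52 in the library labelled UAS:Nr2f5 (percentile 3.05, −0.16 under the crest scaling). Between those groups 4 of 13 rose over all genes and 6 adjusted over the list alone, among them the ligand gene fgf10a (3.27 ± 1.17 against 0.0987 RPM) and the Ets genes etv4 (3.26-fold) and etv5b (2.27-fold). In the retinoic acid list 5 of 17 rose and 2 fell in the mutants against that library (6 and 2 adjusted over the list alone). The receptor gene rargb rose 3.62-fold, the binding protein gene crabp2b 3.32-fold and cyp26b1, whose product degrades retinoic acid, 2.73-fold, while meis2b and rdh10a fell 2.47-fold and 6.46-fold. That list's medians were −0.14 (percentile 55.0) in the library labelled UAS:Nr2f5 and 0.10 (percentile 61.5) in the mutants, each against the control, and both turn in sign under the crest scaling (0.21 and −0.29).

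Hedgehog and Wnt genes had medians of −0.27 (percentile 32.9) and −0.33 (percentile 16.6) in the library labelled UAS:Nr2f5, which became 0.08 and 0.02 under the crest scaling. In the mutants they were 0.15 (percentile 72.9; −0.24 under the crest scaling) and −0.11 (percentile 13.4). Against that library gli2a, a Hedgehog transcription factor, rose 2.24-fold in the mutants, shha fell 4.86-fold and wnt5b rose 2.17-fold, with 3 of 11 Hedgehog genes risen and 1 fallen, and 2 of 12 Wnt genes risen. The Bmp list was at 0.13 (percentile 95.4) in the library labelled UAS:Nr2f5. Of its 15 measured members, 3 were at least 2-fold higher there and 2 lower, among the latter the antagonist gene nog2, 2.81-fold lower (1.85 to 4.45). The immediate early and heat shock list was at 0.14 there (percentile 100), with hsp70.1 4.61-fold higher (3.43 to 6.29), and at 0.17 in the mutants (percentile 87.8). Endothelial genes, 8 of 23 measured, were at 0.29 (percentile 82.3) and −0.89 (percentile 0.22), with 3 fallen adjusted over the list alone in the mutants and 0 over all genes. kdrl, the VEGF receptor gene of vessels, was at 6.28 ± 1.72 RPM in the mutants, 5.81 in the control and 17.9 in the library labelled UAS:Nr2f5. White blood cell genes were at 0.28 (percentile 80.2) and −1.31 (percentile 0.01), with 5 of 8 fallen adjusted over the list alone and 0 over all genes. Red blood cell genes were at −0.46 (percentile 7.53) and glia at 0.15 (percentile 65.8) in the library labelled UAS:Nr2f5. In the mutants the otic, eye and lens list was at −1.24 with 1 of 11 fallen over all genes (crybb1, 16.0-fold) and 7 over the list alone, the pigment list at −0.33 (percentile 10.2) with 0 of 12 over all genes and 2 over the list alone, and the bone list at −0.12 (percentile 5.21), where col1a1b fell 3.13-fold. Cartilage and proliferation medians were 0.13 (percentile 68.8) and 0.05 (percentile 24.3), and the nr2f family's was −0.36 (percentile 25.7) in the library labelled UAS:Nr2f5 and 0.05 (percentile 34.6) in the mutants.

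The tests in the remaining text, apart from the percentile of the lower jaw list, were chosen after the results had been seen. The first pattern is the low level of lower jaw genes in the library labelled UAS:Nr2f5. Counting error is argued against, since it would fall alike on random lists matched on expression and the list's median lay at percentile 0.11 of these. Dilution by other cells, which the fli1a:GFP and sox10:DsRed gate should remove but whose muscle and epidermal genes were higher there, would lower all crest genes alike: the whole-list medians of lower jaw and early neural crest genes differed by −0.355 (two-sided permutation test over genes, p = 0.238) and those of lower and upper jaw genes by −0.5503 (p = 0.0919), which leaves it open for the list. For the 10 members at least 2-fold lower the values cannot decide, since these members were picked by that difference. The 29 upper jaw and early neural crest genes were not picked so, and their median was −0.1711 (95% sign-test interval −0.53 to 0.10). As a set they were not 2-fold lower, but a 2-fold dilution lowers log2(RPM + 1) by less than 1 at low RPM. Whether the other cells express some of the 29 genes was not tested. Dilution as the whole cause or a part of it thus stays open for the 10. Variation between single libraries beyond counting error stays open as well, with 1 library in each group and a chi-square of 10.4 per gene between the 2 mutants, where counting error alone gives about 1. A swap of labels between the 2 sox10:Gal4 libraries stays open, with nr2f5 at a ratio of 1.0517 (0.920 to 1.199). So does the hypothesis that Nr2f5 may lower these genes, since each group is 1 library. The ratio shows no gain at the nr2f5 gene, but whether reads of the transgene are assigned to that gene is not known.

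The second pattern is the low level of muscle, epidermal, blood and neuronal genes in the mutants. A mixture of other cells taken away in a single proportion stays open, as the test made of it cannot decide. The muscle and red blood medians differed by −2.5053 (−4.93 against −2.43, two-sided permutation test over genes, p = 3e-05). These medians cover members with at least 5 RPM in the control, at a pseudocount of 0.1. Genes of the same cell type are not independent replicates, and the control is a single library. The test also assumes that the sorted crest cells do not express these genes, which was not measured. More cells of other types, passed by the gate, in the control is a candidate explanation that stays open, as the tables hold no measure of cell shares apart from the genes of the pattern. An effect of losing Nr2f2 and Nr2f5 in the sorted cells cannot be told apart from a difference between sorts. The labels name no control from the same clutch and sort. Nor can it be told apart from effects of the control's sox10:Gal4 driver and fin biopsy, which the labels do not give for the mutants. The early neural crest median of 0.4526 decides none of these. Summed muscle values also differed between the control (1635 RPM) and the library labelled UAS:Nr2f5 (5339 RPM), neither of which is mutant.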
